A study of Arabidopsis thaliana with 12 samples.

How the data were processed

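Transcript levels were measured in whole wild-type Arabidopsis seedlings of the Columbia ecotype on 12 Affymetrix arrays, 1 per RNA sample. The arrays fall into 4 treatments of 3 biological replicates: no addition (control), 0.2 µM sulfamethoxazole (SMX), 10 mM sucrose, and both together. SMX is a sulfonamide that inhibits dihydropteroate synthase, an enzyme of folate synthesis. Per the labels' protocols, seeds were kept in liquid MS medium in foil-covered 24-well plates for 3 days at 4 °C, were lit for 6 h, and then grew for 3 days at 21 °C. Whether the foil was put back after the light is not stated there. Total RNA was isolated with RNeasy and biotin-labelled by the one-cycle target method, per the labels' protocols.

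The deposited values are log2 expression values, 1 per probe set and array, for 22810 probe sets. The submitters' processing notes name GCRMA and limma, with neither a version nor an order of steps. The log base is not written with the values. It was read as log2 from the range, 2.118 to 15.67, with the same lowest value on every array. A change from or to a group at that floor is a lower bound, and one from or to a group near it is not an exact size. The 64 Affymetrix control probe sets were kept out of the tests, which left 22746. Array medians lay between 5.633 and 5.842 and no pair of arrays was identical. No probe set carries a count of molecules, so precision is limited by the 3 arrays per treatment.

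Gene names came from the platform's annotation, updated through gene IDs to the TAIR10.1 annotation, which served for names alone. Of the 22746 probe sets, 13513 were paired with 1 gene, 503 with several and 8730 with none, and 13436 of the 13513 matched a current locus. Only probe sets paired with 1 gene are named. Probe sets can also bind transcripts of close paralogs, which was not tested.

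All 12 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with the 4 treatments as groups, since 3 arrays a group give few degrees of freedom. The 6 contrasts were SMX alone against control, sucrose alone against control, both against control, both against sucrose alone, both against SMX alone, and the interaction, which is the SMX difference with sucrose minus the SMX difference without it. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided. A limma F test asked in addition whether the 4 groups differed. The treatments, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

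The naming rule took probe sets of 1 gene with a call, a mean of at least 5 in the higher group and no overlap between the arrays compared (overlap was not asked of the interaction). It named the 8 largest rises and 8 largest falls for SMX alone, sucrose alone, both against control and the interaction, and the 4 and 4 largest for the remaining contrasts. For each gene list past its test or with at least 3 called members it also named the 3 called members with the smallest p. The 2 genes of the SMX target enzyme, AT4G30000 and AT1G69190, were always named.

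Gene lists were tested with limma's camera (preset correlation 0.01), Benjamini-Hochberg adjusted over the lists of a contrast. A list needed 3 measured probe sets. Of 21 lists with 375 distinct genes, 61 genes could be matched to the arrays and 10 lists could be tested: auxin response, folate and one-carbon metabolism, methionine and methyl cycle, nucleotide synthesis, cell cycle and DNA replication, genes induced by sugar starvation, flavonoid synthesis, photosynthesis and chlorophyll, seed oil breakdown, and cell wall growth. The 11 others had 0 to 2 matched genes. An unmatched gene may still have a probe set among the 8730 paired with no gene, so it was not followed rather than not measured. Camera with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance, were run beside it. A further 31 lists of gene families and cell components were drawn up after the coverage was known and before their values were tested, and were adjusted as their own family.

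Labelling was described per array by the log2 difference between the 3′ and the 5′ probe sets of the same RNA: for the Bacillus subtilis transcripts dap, lys, phe (averaged as the spike score) and thr, which Affymetrix supplies to be added to the RNA, and for actin, GAPDH and ubiquitin. Arrays with and without sucrose were compared on 14 measures, namely such differences, single 5′ or 3′ levels, the hybridization controls, 25S rRNA and the first principal component, by exact two-sided permutation tests over 924 arrangements, with Benjamini-Hochberg adjustment. The fit was then repeated with the spike score, or the actin score, as a covariate. The adjusted sizes extend slopes on the score within groups (spike score SD 0.404 to 1.61) across its difference of −4.02 between sucrose and control arrays. A kept or a smaller size therefore does not tell labelling from a response. These covariate fits, and a fit without control replicate 1 and sucrose replicate 1, were chosen after seeing the data.

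Other alternatives were a replicate block, median centring, quantile normalization, filters at a mean log2 value above 4 or above 6, a trend and robust variance prior, array weights, probe sets of 1 gene alone, a change of at least 1, fits of the 6 arrays compared, and leaving out each array in turn. Calls of SMX alone and sucrose alone, which share the control arrays, were compared with 100 simulations of unchanged groups. The fit was tested on simulated data with known changes, with spreads taken from the fit to the real arrays. For sucrose alone against control it recovered 32.8% of simulated log2 changes of 0.5, 46.3% of changes of 1 and 87.9% of changes of 2 among 22746 probe sets. With the spike score as a covariate it recovered 16.4%, 17.9% and 40.9%. The changed probe sets were drawn from all those tested, including those at the floor with little spread. Recovery among expressed probe sets alone was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.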

Results

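The series asked how sucrose and SMX, given alone or together, altered transcript levels in young seedlings. Each of the 12 arrays gave values for 22746 probe sets that were not Affymetrix controls, with 3 arrays per treatment. Limma's F test with Benjamini-Hochberg adjustment found 7043 of them (31%) to differ among the 4 treatments. With a labelling score as a covariate it found 109 (spike score) or 165 (actin score), and among probe sets of 1 gene alone 3581.

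With sucrose alone, the matched genes that plants use when sugar is scarce read lower than in the control. Genes of cell walls and glycolysis read higher. Of the 26 genes of the sugar starvation list, 5 could be matched to probe sets, mostly enzymes of amino acid breakdown. All 5 fell with sucrose alone, 5 of 5 also when adjusted over the list alone. How the other members of the list changed was not seen. MCCA, a subunit of the leucine-degrading methylcrotonyl-CoA carboxylase, went from 11.2 ± 0.14 to 8.85 ± 0.99 (SD, n = 3), a log2 change of −2.32 (SE 0.412; limma, Benjamini-Hochberg adjusted p = 0.0054). AKINBETA1, a subunit of the energy-sensing kinase SnRK1, changed by −1.82 (SE 0.255), and AT4G33150, a lysine breakdown enzyme, by −1.73 (SE 0.277), with limma and Benjamini-Hochberg adjusted p = 0.00215 and 0.00357. IVD and MCCB, further enzymes of leucine breakdown, changed by −1.05 and −0.81. The list's median change was −1.73 (limma's camera, Benjamini-Hochberg adjusted p = 0.00156; adjusted p = 0.145 with an estimated correlation). With the labelling scores as covariates the median was −0.99 (spike, adjusted p = 0.00667) and −1.29 (actin, adjusted p = 0.00485; limma's camera with Benjamini-Hochberg adjustment), and 0 of the 5 genes stayed called alone (limma, Benjamini-Hochberg adjusted p from 0.361 to 0.505 with the spike score and from 0.228 to 0.557 with the actin score). MCCA was then −1.49 (SE 0.782) with the spike score, and AT4G33150, IVD and MCCB kept most of their change (−1.57, −0.94 and −0.78) at SEs of 0.572, 0.452 and 0.388.

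**Figure D1:**
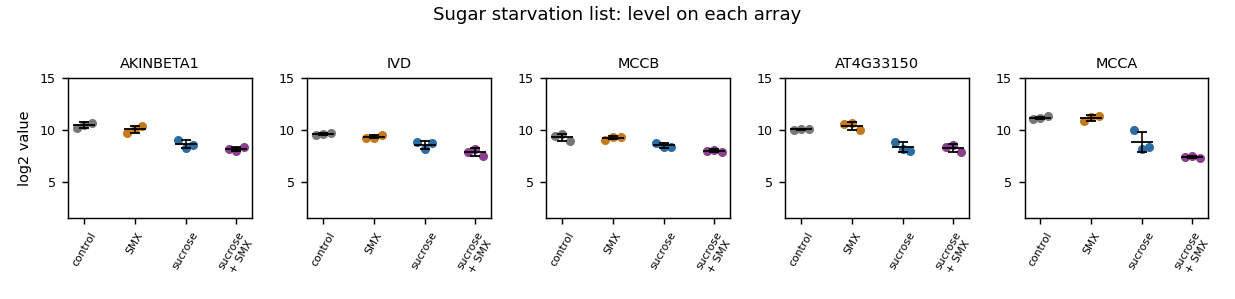
Log2 expression of the 5 measured sugar starvation genes on each of the 12 arrays, by treatment. Points are arrays and bars show the mean ± SD of 3 arrays, and MCCA fell from 11.2 in the control to 8.85 with sucrose and 7.39 with both.

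Cell wall growth genes moved the other way. The list's median rose by 1.40 with sucrose alone (5 probe sets, 3 up over all probe sets and 5 up when adjusted over the list alone). Limma's camera gave a Benjamini-Hochberg adjusted p = 0.00419, against adjusted p = 0.145 with an estimated correlation, adjusted p = 0.32 with the spike score, 0.213 with the actin score and 0.0572 at a mean log2 value above 6. EXPA8, an expansin that loosens walls, went from 6.84 ± 0.75 to 9.73 ± 0.35 (SD, n = 3), a change of 2.89 (SE 0.452), and XTH20, a xyloglucan-modifying enzyme, rose by 1.40 (SE 0.278). Neither stayed called with the spike score (limma, Benjamini-Hochberg adjusted p = 0.448 and 0.157) or the actin score (0.329 and 0.159). EXPA8 shrank to 1.74 (SE 0.805) with the spike score, while XTH20 was 2.11 (SE 0.491). XTH33 rose by 1.64 (SE 0.457), but its change was −0.43 with the spike score, and its call ended without control replicate 2 (adjusted p = 0.0826), control replicate 3 (0.082), sucrose replicate 1 (0.0534), sucrose replicate 2 (0.102), sucrose replicate 3 (0.0886) or sucrose plus SMX replicate 1 (0.051), by limma with Benjamini-Hochberg adjustment. The wider families, which by name take in EXPA8, XTH20 and XTH33, moved unevenly. Expansins had a median of 2.67 (10 probe sets, 7 up, 0 down) and XTH genes of 0.66 (9 probe sets, 3 up, 1 down). Their camera tests in limma gave Benjamini-Hochberg adjusted p = 0.000507 and 0.0483, and adjusted p = 0.232 and 0.298 with estimated correlations. The root hair expansins EXPA7 and EXPA18, the measured part of the untested root hair list, rose by 2.75 (SE 0.307) and 3.96 (SE 0.297). With the spike score EXPA7 was 2.79 with about double the SE (0.637; not called, limma, Benjamini-Hochberg adjusted p = 0.153), and EXPA18 shrank to 2.81 (SE 0.383) and stayed called (adjusted p = 0.046). With the actin score they were 2.89 (SE 0.579; adjusted p = 0.0716) and 3.14 (SE 0.436; adjusted p = 0.0236, limma, Benjamini-Hochberg).

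Of 11 glycolysis probe sets, 9 rose and 1 fell with sucrose alone, with a median of 1.42 (limma's camera, Benjamini-Hochberg adjusted p = 4.83e-05; adjusted p = 0.29 with an estimated correlation). AT1G12000, a subunit of pyrophosphate-dependent phosphofructokinase, rose by 3.28 (SE 0.565), AT5G42740, phosphoglucose isomerase, by 2.41 (SE 0.442) and GAPC2, cytosolic glyceraldehyde-3-phosphate dehydrogenase, by 1.46 (SE 0.28). The array's GAPDH control probe sets averaged 13.1 in the control and 13.4 with sucrose at the 3′ end, and 7.86 and 12.1 at the 5′ end. Among 54 class III peroxidase probe sets 21 rose and 1 fell (median 0.061, mean 0.73; limma's camera, Benjamini-Hochberg adjusted p = 0.00108; adjusted p = 0.0889 with an estimated correlation). Of 8 autophagy genes 6 fell, with a median of −0.96 (adjusted p = 0.0267, or adjusted p = 0.54 with an estimated correlation, by limma's camera with Benjamini-Hochberg adjustment). ATG8E, whose product coats autophagosomes, changed by −1.41 (SE 0.256). None of the 4 genes named here from glycolysis and autophagy stayed called with the spike score (limma, Benjamini-Hochberg adjusted p from 0.579 to 0.783) or the actin score (0.435 to 0.579), and with the spike score all 4 shrank, to 1.13 (SE 0.741), 0.70 (SE 0.564), 0.45 (SE 0.394) and −0.76 (SE 0.455). With the spike score as a covariate the medians were 0.61 for glycolysis, 1.44 for expansins, 0.20 for peroxidases and −0.39 for autophagy genes. With the actin score they were 0.71, 1.45, 0.20 and −0.35. Autophagy genes (adjusted p = 0.542 and 0.364) and XTH genes (adjusted p = 0.55 and 0.364) no longer passed limma's camera test with Benjamini-Hochberg adjustment under either score.

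Among probe sets of 1 gene that met the naming rule, the largest rises with sucrose alone were those of AT4G05150 (6.02, SE 0.708), the jacalin-related lectins AT1G52070 (5.38, SE 0.423) and AT1G52060 (5.0, SE 0.397), the lipid transfer family protein AT3G53980 (5.10, SE 0.289), AT5G13030 (4.92, SE 0.708), AT4G16490 (at least 4.87, its control mean of 2.12 being the floor of the values), the berberine bridge enzyme-like AT1G30760 (4.80, SE 0.576) and the peroxidase AT5G19890 (4.76, SE 0.45). AT3G53980, for example, went from 5.76 ± 0.44 to 10.9 ± 0.39 (SD, n = 3). The 2 lectins are close paralogs whose probe sets were not checked for shared binding. The largest falls under the same rule were those of AT2G03850 (−3.92, SE 0.408), a late embryogenesis abundant family member, AT5G48490 (−3.55, SE 0.67), AT3G19800 (−3.41), AT1G15010 (−3.21), the clock-regulated CCL (−3.06, SE 0.475), AT2G01870 (−3.04), CRR42 (−3.0, SE 0.39), which helps assemble the chloroplast NDH complex, and the glutaredoxin AT5G18600 (−2.97, SE 0.216). Limma with Benjamini-Hochberg adjustment gave adjusted p from 5.08e-05 to 0.0069 for these 16 genes. Only AT3G53980 stayed called with the spike score (6.04, limma, Benjamini-Hochberg adjusted p = 0.00892). Several others kept their size with the spike score while their SE rose, among them AT1G52070 (5.13, SE 0.873), AT1G52060 (5.37, SE 0.809), AT5G19890 (4.68, SE 0.934), AT2G03850 (−3.79, SE 0.846) and CCL (−2.96, SE 0.987). Others shrank, such as AT1G30760 (2.33, SE 0.59) and AT5G48490 (−1.39, SE 1.05). Neither a kept nor a smaller size tells labelling from a response. AT3G53980 also stayed called with the actin score, as did AT1G52070, AT1G52060, AT5G19890 and AT5G18600 (limma, Benjamini-Hochberg adjusted p from 0.000789 to 0.0494).

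In all, 5336 probe sets were called for sucrose alone, 2705 up and 2631 down (23.5% of those tested), with 8066 at an unadjusted p under 0.05. The 3 sucrose arrays and 3 control arrays did not overlap for 34.9% of probe sets, where chance gives 10% without tied values and less with values tied at the floor. Without control replicate 2, sucrose replicate 2 or sucrose replicate 3 the count was 3538, 3284 or 3364, and 1856 when only the 6 arrays compared were fitted. Of the 5336, 3328 changed by at least 1, and a fit of the probe sets of 1 gene called 2691. With the spike score as a covariate 65 probe sets were called (72.3% up) and with the actin score 251 (69.7% up). The median size of the 5336 went from 1.17 (median SE 0.238) to 0.76 (0.437) with the spike score and 0.77 (0.383) with the actin score, and 96.9% and 98.3% kept their sign. The spike score itself was lower by a log2 difference of −4.02 in the sucrose arrays than in the control arrays. Median centring shifted the median change of all probe sets to −0.109.

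**Figure D2:**
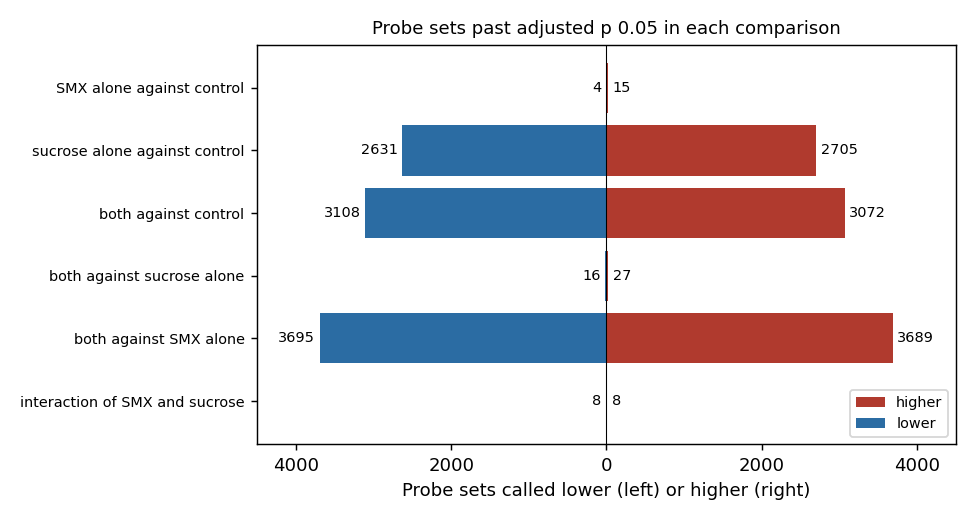
Number of probe sets called up and down in each of the 6 comparisons (limma, 22746 probe sets, 3 arrays per group). Comparisons between arrays with and without sucrose called 5336 to 7384 probe sets, and comparisons within a sucrose level and the interaction 16 to 43.

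Genes around the folate pathway, which SMX inhibits, changed in both directions with sucrose alone. FOLB1 and FOLB2, dihydroneopterin aldolases of folate synthesis, changed by −1.81 (SE 0.236) and −1.03 (SE 0.222), while AT3G12290, a methylenetetrahydrofolate dehydrogenase, rose by 1.40 (SE 0.28; limma, Benjamini-Hochberg adjusted p = 0.00163, 0.012 and 0.00887). In the folate list 2 probe sets rose and 3 fell (3 and 3 when adjusted over the list alone). None of these 3 genes was called with the spike or the actin score, and with the spike score they were −1.18 (SE 0.411), −0.29 (SE 0.339) and 0.61 (SE 0.476). Nucleotide synthesis genes had a median of 0.60 with 2 of 5 up (2 when adjusted over the list alone). Their limma camera test gave a Benjamini-Hochberg adjusted p = 0.0288, with adjusted p = 0.145 with an estimated correlation, 0.0925 with the spike score, 0.213 with the actin score, 0.0668 after quantile normalization, and 0.191 and 0.19 at a mean log2 value above 4 and above 6. AT2G35040, which completes purine synthesis, rose by 0.69 (SE 0.134) and AT1G63660, GMP synthase, by 0.92 (SE 0.22; limma, Benjamini-Hochberg adjusted p = 0.00776 and 0.0184, the second 0.0674 without sucrose replicate 3 and 0.0564 without control replicate 1 and sucrose replicate 1 together). The 2 were 0.65 (SE 0.278) and 1.18 (SE 0.444) with the spike score, with adjusted p = 0.436 and 0.372, and had adjusted p = 0.476 and 0.599 with the actin score (limma, Benjamini-Hochberg).

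Auxin response genes also split with sucrose alone. GH3.3, which conjugates auxin to amino acids, went from 9.11 ± 0.82 to 7.05 ± 0.22 (SD, n = 3), a change of −2.05 (SE 0.352), and IAA29, an auxin signalling repressor, changed by −1.58 (SE 0.273; limma, Benjamini-Hochberg adjusted p = 0.00466 and 0.00482). GH3.1 rose by 2.55 (SE 0.589; adjusted p = 0.0156) from 2.21 ± 0.023 (SD, n = 3), near the floor, but was not called without sucrose replicate 2 (adjusted p = 0.0606) or sucrose replicate 3 (0.0545, limma with Benjamini-Hochberg adjustment). None of these 3 genes was called with the spike or the actin score, though GH3.3 was −2.99 (SE 0.615) and IAA29 −1.61 (SE 0.567) with the spike score, and GH3.1 1.77 (SE 1.18). The auxin list had a median of −0.029, a mean of 0.039 and an upward test (2 up and 2 down when adjusted over the list alone).

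The lists for auxin response (adjusted p = 0.983), folate (0.983, median −0.048), methionine (0.983), cell cycle (0.983), flavonoid synthesis (0.983), photosynthesis (0.983) and seed oil breakdown (0.983) did not pass limma's camera test with Benjamini-Hochberg adjustment for sucrose alone. The methionine list had a median of −0.079 against a mean of 0.38, photosynthesis −0.028 against 0.060. MMT, which makes S-methylmethionine, rose by 1.66 (SE 0.277), and AIM1, of fatty acid oxidation, by 1.95 (SE 0.578), each the only called member of its list and called with neither score (0.88, SE 0.473, and 0.24, SE 0.956, with the spike score). Of the lists too small to test, sugar-induced genes were represented by APL3 (−0.034) and APL4 (−0.070), seed storage by OLEO3 (0.060), ribosomes by AT3G09630 (0.68) and AT2G19730 (0.16) and defence by PDF1.2 (−0.28), none called for sucrose alone. The detoxification gene GSTU25 rose by 1.45 (SE 0.248; limma, Benjamini-Hochberg adjusted p = 0.00458, and 1.58, SE 0.513, adjusted p = 0.304 with the spike score), and COR15A of the abscisic acid list lay at the floor, 2.12, in each group. Auxin transport, DNA damage, root meristem and ethylene had 0 genes matched through the annotation, so their genes could not be followed.

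**Figure D3:**
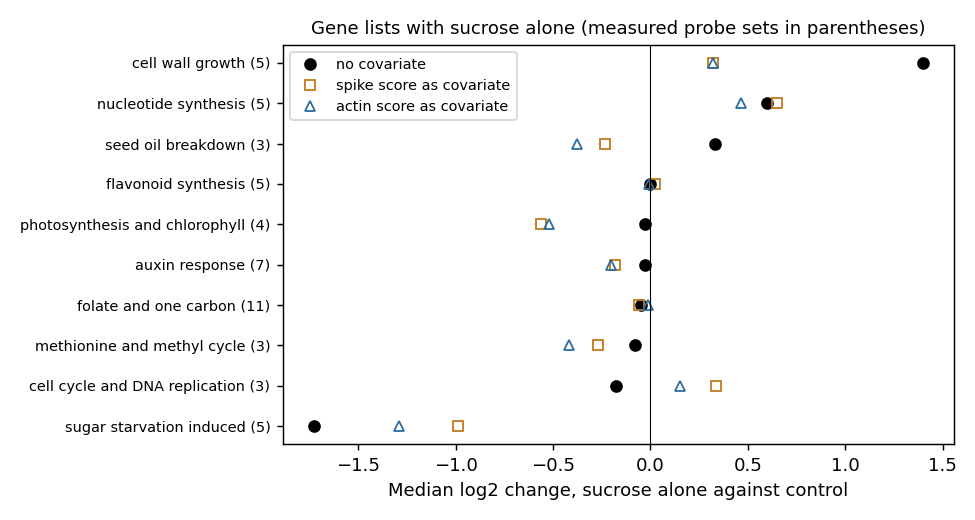
Median log2 change of the tested gene lists for sucrose alone against control, without a covariate and with the spike or the actin score as a covariate. The starvation list lay at −1.73, −0.99 and −1.29, and cell wall growth at 1.40, 0.32 and 0.32.

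Few probe sets were called for SMX alone at this dose, in a comparison that recovered 31.3% of simulated log2 changes of 0.5 and 52.2% of changes of 1. These shares include probe sets at the floor, whose small spread makes recovery easier, so they do not give the recovery among expressed probe sets. AT2G16630 rose from 7.99 ± 0.037 to 9.26 ± 0.22 (SD, n = 3), a log2 change of 1.28 (SE 0.137; limma, Benjamini-Hochberg adjusted p = 0.0166). AT1G76590, a PLATZ-domain protein of a zinc-binding family, fell from 6.17 ± 0.031 to 5.37 ± 0.067 (SD, n = 3), a change of −0.80 (SE 0.0443; limma, Benjamini-Hochberg adjusted p = 0.000925). Only these 2 genes met the naming rule. The call of AT2G16630 ended without sucrose replicate 2 (adjusted p = 0.0518), sucrose plus SMX replicate 1 (0.0516) or sucrose plus SMX replicate 3 (0.0584), and at a mean log2 value above 4 (0.113) or above 6 (0.0671); that of AT1G76590 ended at a mean above 4 (0.291, limma with Benjamini-Hochberg adjustment). The target enzyme gene AT4G30000 was 5.23 ± 0.21 in the control and 5.19 ± 0.3 with SMX (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 1), and AT1G69190 lay at the floor, 2.17 and 2.12.

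In all, 19 probe sets were called for SMX alone, 15 up and 4 down, and 1510 had an unadjusted p under 0.05. The higher mean was under 5 for 14 of the 19. Groups did not overlap for 7.46% of probe sets, where chance gives 10% without tied values. Ties at the floor lower the chance share by an amount that was not computed. With a mean log2 value above 4 or above 6, or in a fit of the 6 arrays compared, the count was 0, after median centring 9 and among probe sets of 1 gene 10 (60% up). Of the 19, 7 changed by at least 1. Leaving out single arrays gave 64 (control replicate 1, 15 up and 49 down), 35 (control replicate 3, 57.1% up), 44, 68 and 70 (SMX replicates 1, 2 and 3; 93.2%, 86.8% and 90% up), 11 and 12 (sucrose replicates 2 and 3), and 12 and 9 (sucrose plus SMX replicates 1 and 3). Without control replicate 1 and sucrose replicate 1 together it was 40, with 22.5% up in place of 78.9%. The spike score differed by 0.73 between SMX and control arrays.

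None of the 10 lists passed limma's camera test for SMX alone with Benjamini-Hochberg adjustment. The smallest p was that of methionine and methyl cycle genes, with a median of −0.36 (adjusted p = 0.0759, limma's camera, Benjamini-Hochberg; 1 down when adjusted over the list alone). The auxin list had 1 gene up when adjusted over the list alone. Without control replicates 1, 2 or 3, or sucrose replicate 2, the number of lists passed was 2, 1, 2 and 1. Folate genes had a median of −0.044, nucleotide genes of −0.034 (mean 0.023, test downward) and cell wall genes of 0.22 (mean −0.085, test upward). Among the added families, chloroplast-encoded genes (69 probe sets, median 0.50) and core histones (9, median 0.34) shifted upward with limma's camera and Benjamini-Hochberg adjusted p = 0.000109 and 0.00398. With estimated correlations these were adjusted p = 0.721 and 0.595. The BGLU and GSTU families had medians of 0.16 and 0.14 (adjusted p = 0.00643 and 0.0473, or adjusted p = 0.594 and 0.595 with estimated correlations, by the same limma and Benjamini-Hochberg test). No member of these 4 families was called, and GSTU did not pass with the spike score (adjusted p = 0.138) or the actin score (0.1).

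In the presence of sucrose, a small set of genes rose with SMX. Some probe sets with no gene in the annotation rose further than those named here, by as much as 5.29. AT5G04120, of the phosphoglycerate mutase family, went from 3.39 ± 0.087 with sucrose to 7.01 ± 0.24 with both (SD, n = 3), a log2 change of 3.63 (SE 0.233). AT2G43620, a chitinase family gene, rose by 2.92 (SE 0.237), AT4G38080 by 2.90 (SE 0.317) and AT1G74010, a strictosidine synthase-like gene, by 2.47 (SE 0.201), with limma and Benjamini-Hochberg adjusted p from 0.00142 to 0.0122 for the 4. Without control replicate 1 and sucrose replicate 1 together, AT4G38080 was no longer called (limma, Benjamini-Hochberg adjusted p = 0.0796). AT5G64120, a class III peroxidase, rose by 1.92 (SE 0.193; limma, Benjamini-Hochberg adjusted p = 0.00856), and AT2G16630 rose again, by 1.47 (SE 0.137; adjusted p = 0.00611, limma, Benjamini-Hochberg). These last 2 were picked out after their values were seen. Across 54 peroxidase probe sets the median was 0.088, with 1 called up and 0 down (limma's camera, Benjamini-Hochberg adjusted p = 0.000471; adjusted p = 0.0465 with an estimated correlation).

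**Figure D4:**
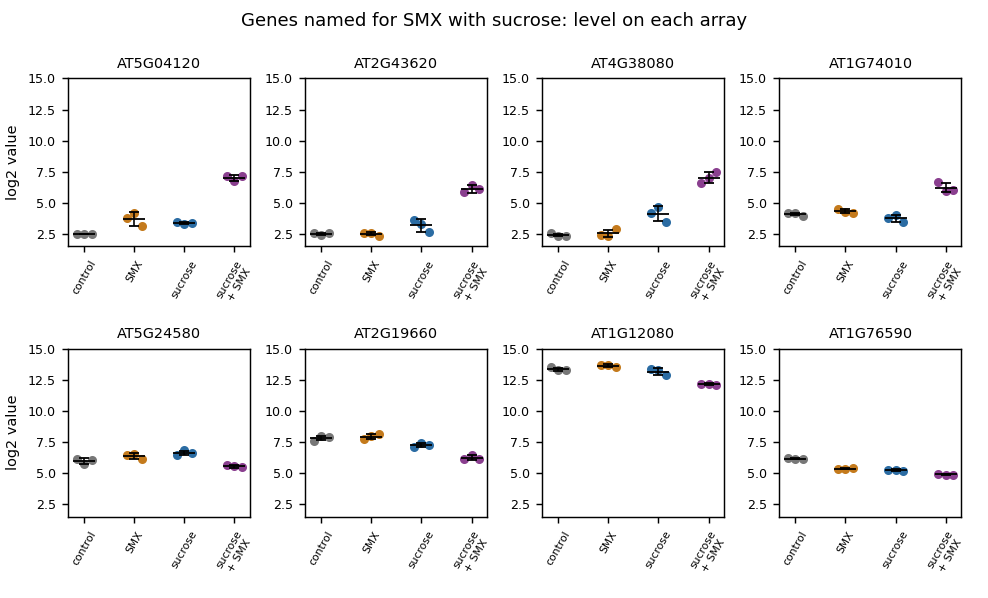
Log2 expression of the 8 genes named for both treatments against sucrose alone, on each of the 12 arrays. Points are arrays and bars show the mean ± SD of 3 arrays, and AT5G04120 stood at 2.45, 3.70, 3.39 and 7.01 in control, SMX, sucrose and both.

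Among probe sets of 1 gene that met the naming rule, 4 fell with SMX in the presence of sucrose. Some probe sets with no gene in the annotation fell further, by as much as −3.53. AT5G24580 changed by −1.08 (SE 0.147), AT2G19660 by −0.995 (SE 0.139), AT1G12080 by −0.99 (SE 0.122) and AT1G76590 by −0.34 (SE 0.0443; limma, Benjamini-Hochberg adjusted p = 0.0323, 0.0384, 0.0224 and 0.0277). The call of AT5G24580 held only without control replicates 1 or 2 or SMX replicate 3, and without each of the 9 other arrays adjusted p lay between 0.0568 and 0.129. AT2G19660 held only without control replicate 1 or sucrose plus SMX replicate 2 (10 other arrays, 0.0555 to 0.144). AT1G12080 held only without control replicates 1 or 3, SMX replicate 3 or sucrose replicate 3 (8 others, 0.0519 to 0.0938), and AT1G76590 only without control replicate 1, SMX replicate 3, sucrose replicate 3 or sucrose plus SMX replicate 1 (8 others, 0.0519 to 0.101). Quantile normalization ended the calls of AT2G19660, AT1G12080 and AT1G76590 (limma, Benjamini-Hochberg adjusted p = 0.0538, 0.0589 and 0.155), median centring and a mean log2 value above 4 that of AT1G76590 (adjusted p = 0.231 and 0.681), and the spike score those of AT5G24580, AT2G19660 and AT1G76590 (limma, Benjamini-Hochberg adjusted p = 0.0714, 0.0706 and 0.062), with sizes unchanged at −1.08 (SE 0.155), −0.997 (SE 0.143) and −0.34 (SE 0.047). Without control replicate 1 and sucrose replicate 1 together all 4 ended (0.0804, 0.0589, 0.0796 and 0.146 in the order first given). With the actin score all 4 ended (adjusted p from 0.059 to 0.0607, limma, Benjamini-Hochberg).

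As a list, starvation genes shifted down between sucrose and both in limma's camera with the preset correlation alone. Their median was −0.53 (limma's camera, Benjamini-Hochberg adjusted p = 0.000149; adjusted p = 0.254 with an estimated correlation and 0.152 with fry), with 0 called over all probe sets and 3 down when adjusted over the list alone. MCCA stood at 8.85 ± 0.99 with sucrose and 7.39 ± 0.096 with both (SD, n = 3; not called, limma, Benjamini-Hochberg adjusted p = 0.439). Auxin response genes had a median of −0.23 (camera adjusted p = 0.0112, limma, Benjamini-Hochberg; adjusted p = 0.342 with an estimated correlation and 0.327 with fry), 0 called and 1 down when adjusted over the list alone. The auxin shift did not pass without sucrose plus SMX replicate 1 (limma's camera, Benjamini-Hochberg adjusted p = 0.283), leaving 1 list, nor at a mean log2 value above 4 (0.337) or above 6 (0.297), nor without control replicate 1 and sucrose replicate 1 together (0.0538). IAA29 was 6.15 ± 0.4 with sucrose and 4.69 ± 0.35 with both (SD, n = 3; not called, limma, Benjamini-Hochberg adjusted p = 0.123). Ribosomal proteins (107 probe sets, median 0.077) and GSTU genes (median 0.013) had limma camera tests with Benjamini-Hochberg adjusted p = 0.00422 and 0.0356, and adjusted p = 0.643 for each with estimated correlations, GSTU also 0.0612 with the spike score. The other 8 fixed lists had adjusted p from 0.47 to 0.822 by limma's camera with Benjamini-Hochberg adjustment, and in 3 of them, cell cycle, seed oil breakdown and cell wall growth, the sign of the median (0.019, 0.068 and −0.0070) opposed that of the test. When adjusted over the list alone, 1 cell wall gene rose and 1 fell.

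In all, 43 probe sets were called for both against sucrose alone, 27 up and 16 down, with 1256 at an unadjusted p under 0.05. Groups did not overlap for 9.7% of probe sets, where chance gives 10% without tied values. With ties at the floor chance gives less, so whether 9.7% exceeds it was not determined. The count was 28 without SMX replicate 2 and 26 without sucrose replicate 2, 66 at a mean log2 value above 4 (48.5% up), 193 with array weights (50.3% up), 22 among probe sets of 1 gene and 0 when only the 6 arrays compared were fitted. The spike score differed by 0.040 between these groups, too little for it to alter sizes as a covariate, and 32 of the 43 probe sets were called again with it. The actin score differed by −0.33, and 27 were called again with it. AT4G30000 was 4.55 ± 0.17 with sucrose and 4.02 ± 0.045 with both (SD, n = 3), a change of −0.53 that was not called (limma, Benjamini-Hochberg adjusted p = 0.519).

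The interaction asked whether SMX acted differently with and without sucrose. AT2G43620 was 2.49 ± 0.1 and 2.50 ± 0.12 without sucrose, control and SMX, and 3.19 ± 0.5 and 6.10 ± 0.29 with it (SD, n = 3), an interaction of 2.91 (SE 0.336). AT5G40590, a C1 domain gene, stood at 5.64 ± 0.35, 5.68 ± 0, 5.66 ± 0.068 and 8.01 ± 0.32 in the order control, SMX, sucrose and both (SD, n = 3; interaction 2.31, SE 0.267), and AT1G74010 at 4.09, 4.31, 3.74 and 6.21 (2.25, SE 0.284). AT5G42250, an alcohol dehydrogenase family gene, stood at 8.11, 8.75, 7.91 and 7.0 (−1.56, SE 0.199; limma, Benjamini-Hochberg adjusted p = 0.0397, 0.0397, 0.0488 and 0.0488 for the 4). AT2G43620 lay near the floor without sucrose and AT5G40590 had 1 value on all 3 SMX arrays, so neither was clearly above background there and these 2 interactions are not exact log2 differences. All 4 fell short of the threshold with the spike score (adjusted p = 0.0684, 0.0541, 0.096 and 0.096, limma, Benjamini-Hochberg), the actin score (0.0854, 0.0738, 0.0982 and 0.0982) and on leaving out single arrays. Their sizes stayed with the spike score, at 2.91 (SE 0.365), 2.40 (SE 0.245), 2.21 (SE 0.301) and −1.57 (SE 0.215). AT1G74010 held only without sucrose plus SMX replicate 1 and AT5G42250 only without SMX replicate 3 (11 other arrays each, adjusted p from 0.0644 to 0.105 and from 0.0548 to 0.131). AT2G43620 ended without control replicates 1, 2 or 3, SMX replicate 1, sucrose replicate 2 or sucrose plus SMX replicates 2 or 3 (0.0684 to 0.0961). AT5G40590 ended without control replicate 2, SMX replicate 1, any sucrose replicate or sucrose plus SMX replicates 1 or 3 (0.0644 to 0.0961, limma with Benjamini-Hochberg adjustment). Quantile normalization ended AT5G40590, AT1G74010 and AT5G42250 (adjusted p = 0.0506, 0.0506 and 0.0646), array weights AT1G74010 and AT5G42250 (0.0742 and 0.0524), and a mean log2 value above 4 AT5G42250 (0.0504). Leaving out control replicate 1 and sucrose replicate 1 together ended AT5G40590, AT1G74010 and AT5G42250 (0.0617, 0.157 and 0.144).

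The interaction called 16 probe sets, 8 up and 8 down, with 1391 at an unadjusted p under 0.05. For 7 of the 16 no group mean reached 5. Without control replicates 2 or 3 the count was 9 or 10, without SMX replicates 2 or 3 it was 42 (21.4% up) or 48 (25% up), without sucrose replicate 2 it was 7, and without sucrose plus SMX replicates 2 or 3 it was 9 each. Quantile normalization gave 8, the spike score 1, the actin score 2, leaving out control replicate 1 and sucrose replicate 1 together 29, and probe sets of 1 gene 6. The call kept with the spike score was that of a probe set with no gene in the annotation. It stood at 3.01, 3.04, 3.07 and 6.75 in control, SMX, sucrose and both, an interaction of 3.66 (SE 0.205). Its adjusted p was 0.00102, and 0.00642 and 0.00798 with the spike and the actin score (limma, Benjamini-Hochberg). Its 3 lower means were low, so the size is not exact. The median size of the 16 was 1.53 without a score, 1.57 with the spike score and 1.54 with the actin score, and 100% kept their sign.

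As lists, methionine genes (median 0.69), auxin response genes (−0.22) and starvation genes (−0.45) passed limma's camera test for the interaction with Benjamini-Hochberg adjusted p = 0.0142, 0.0142 and 0.039, and adjusted p = 0.21, 0.328 and 0.373 with estimated correlations and 0.101, 0.237 and 0.361 with fry. No member was called in any of them, and adjusted over the list alone 2 auxin genes fell. Without control replicate 3 the auxin list did not pass (adjusted p = 0.189), and without SMX replicate 3 or control replicate 1 neither did methionine (0.0611 and 0.0717). The starvation list ended without control replicates 1 or 3 (0.119 and 0.0969), SMX replicates 2 or 3 (0.087 and 0.132), sucrose replicate 1 (0.0918) or sucrose plus SMX replicate 3 (0.124, limma's camera, Benjamini-Hochberg). The number of lists passed was 1 without control replicate 3 and 1 without SMX replicate 3. At a mean log2 value above 4 it was 0, with adjusted p = 0.243, 0.0532 and 0.0532 for auxin, methionine and starvation. The starvation list did not pass with the spike score (adjusted p = 0.102), the actin score (0.106) or array weights (0.182, limma's camera, Benjamini-Hochberg). Without control replicate 1 and sucrose replicate 1 together methionine and starvation did not pass (0.0828 and 0.271). Ribosomal proteins (median 0.11) and chloroplast-encoded genes (median −0.51) passed among the added families (limma's camera, Benjamini-Hochberg adjusted p = 0.00197 and 0.00335), with adjusted p = 0.906 and 0.922 with estimated correlations, the latter 0.135 with the actin score. The median of the cell cycle list (0.013) and of the cell wall list (−0.22) opposed the sign of their tests (limma's camera, Benjamini-Hochberg adjusted p = 0.816 and 0.867).

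With both treatments against control, a root hair expansin rose and a regulator of root peroxidases fell. EXPA18, an expansin of root hairs, rose from 4.32 ± 0.49 to 9.46 ± 0.2 (SD, n = 3), a change of 5.14 (SE 0.297; limma, Benjamini-Hochberg adjusted p = 4.36e-05), and stayed called with the spike score (4.01, SE 0.38, adjusted p = 0.0086, limma, Benjamini-Hochberg). UPB1, a transcription factor that represses root peroxidases, fell by 3.86 (SE 0.356; limma, Benjamini-Hochberg adjusted p = 0.00025), but was not called with the spike or the actin score (−3.46, SE 0.715, adjusted p = 0.0732 and −2.91, SE 0.586, adjusted p = 0.0587, limma, Benjamini-Hochberg). Of 54 peroxidase probe sets 24 rose and 3 fell (median 0.26; limma's camera, Benjamini-Hochberg adjusted p = 2.44e-05, and adjusted p = 0.0243 with an estimated correlation). The other largest rises among genes under the naming rule were AT1G52070 (6.22), AT4G05150 (5.75), AT3G19430 (5.06), AT1G52060 (5.0), scpl35 (4.99), AT5G13030 (4.89) and AT4G38080 (4.60), and the other largest falls AT2G05540 (−5.27), a glycine-rich protein, the glutamine amidotransferase GAT1_2.1 (−4.91), AT4G10910 (−4.26), CCL (−4.12), AT2G03850 (−4.10), AT3G19800 (−4.05) and AT5G48490 (−3.80), with limma and Benjamini-Hochberg adjusted p from 7.82e-05 to 0.00405. With the spike score AT1G52070, AT3G19430, AT1G52060 and AT4G38080 stayed called (limma, Benjamini-Hochberg adjusted p from 0.0292 to 0.0326). None of the 8 falls did, although AT2G05540 (−5.68, SE 1.08), GAT1_2.1 (−4.80, SE 1.5), CCL (−4.01, SE 0.979) and AT2G03850 (−3.97, SE 0.84) kept their size with the spike score while their SE rose.

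The same lists passed for both against control. Starvation genes had a median of −1.82 (5 of 5 down, 5 when adjusted over the list alone), cell wall genes of 1.34 (3 up, 5 over the list alone) and nucleotide genes of 0.62 (2 up, 3 over the list alone), with limma camera and Benjamini-Hochberg adjusted p = 0.000197, 0.0064 and 0.0191, and adjusted p = 0.114 for each with an estimated correlation. With the spike score these were adjusted p = 0.000166, 0.305 and 0.0628, and with the actin score 0.000167, 0.244 and 0.167. At a mean log2 value above 6 cell wall and nucleotide genes did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.103 and 0.145), and nucleotide genes did not above 4 (0.142). MCCA changed by −3.78 (SE 0.412), AKINBETA1 by −2.26 (SE 0.255), IVD by −1.78 (SE 0.219), XTH20 by 1.89 (SE 0.278), XTH18 by 1.34 (SE 0.223), AT2G35040 by 0.88 (SE 0.134) and AT1G63660 by 0.95 (SE 0.22). None of these 7 was called with the spike score (limma, Benjamini-Hochberg adjusted p from 0.0558 to 0.39) or the actin score (0.0788 to 0.58). IVD (−1.67, SE 0.448), AT2G35040 (0.84, SE 0.275), AT1G63660 (1.21, SE 0.441) and XTH20 (2.60, SE 0.487) kept or gained size with the spike score, and MCCA (−2.96, SE 0.776), AKINBETA1 (−1.44, SE 0.394) and XTH18 (0.84, SE 0.407) lost some. EXPA8 rose by 1.57 (SE 0.452; adjusted p = 0.0322), but not past the threshold without control replicates 2 or 3 (0.0987 and 0.108) or sucrose plus SMX replicates 2 or 3 (0.105 and 0.104, limma, Benjamini-Hochberg) or with either score (0.44, SE 0.799, adjusted p = 0.958 with the spike score).

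Folate genes split in the same comparison, and 3 of 7 auxin response genes fell. IAA29 changed by −3.04 (SE 0.273), GH3.3 by −2.04 (SE 0.352) and LBD29, an auxin-induced regulator of lateral roots, by −0.62 (SE 0.198; limma, Benjamini-Hochberg adjusted p = 0.000214, 0.00369 and 0.0485; with the spike score 0.0536, 0.0723 and 0.536 at changes of −3.07, SE 0.563, −2.97, SE 0.61, and −0.64, SE 0.408). The call of LBD29 held only without SMX replicates 2 or 3 or sucrose plus SMX replicate 2 (9 other arrays, adjusted p from 0.0679 to 0.152) and ended after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0581) and without control replicate 1 and sucrose replicate 1 together (0.102). The auxin list had 0 up and 3 down, also when adjusted over the list alone, with a median of 0.015 against a mean of −0.46, and did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.704). FOLB1 changed by −1.69 (SE 0.236), FOLB2 by −1.34 (SE 0.222) and AT4G30000 by −1.21 (SE 0.161), from 5.23 to 4.02 (limma, Benjamini-Hochberg adjusted p = 0.00145, 0.00304 and 0.00114; with the spike score 0.289, 0.452 and 0.184 at −1.06, SE 0.408, −0.61, SE 0.337, and −1.07, SE 0.327). The folate list had 2 up and 3 down, 3 and 3 when adjusted over the list alone. Lists that did not pass had limma camera tests with Benjamini-Hochberg adjusted p from 0.704 to 0.994, and in flavonoid synthesis the mean (0.032) opposed the test.

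In all, 6180 probe sets were called for both treatments against control (3072 up, 3108 down, 27.2%), with 8576 at an unadjusted p under 0.05. The groups did not overlap for 38.6% of probe sets, where chance gives at most 10%. Of the 6180, 3923 changed by at least 1, and fits of the 6 arrays compared and of probe sets of 1 gene called 3530 and 3108. The spike score as a covariate left 287 (65.5% up) and the actin score 441 (62.8% up). The median size of the 6180 went from 1.19 (median SE 0.236) to 0.84 (0.433) with the spike score. The spike score was lower by a difference of −3.98 in arrays with both treatments. Glycolysis (median 1.65), expansins (2.60), XTH genes (1.2) and autophagy genes (−1.11) again passed the added tests, with limma camera and Benjamini-Hochberg adjusted p from 2.44e-05 to 0.0368, and none of these 4 with an estimated correlation (adjusted p = 0.286, 0.286, 0.286 and 0.511). XTH genes (0.315) and autophagy genes (−0.51) did not pass with the spike score (limma's camera, Benjamini-Hochberg adjusted p = 0.346 and 0.31, and 0.319 and 0.255 with the actin score), and the medians of glycolysis (0.77) and expansins (0.90) shrank but passed. GSTU25 rose by 2.87 (SE 0.248) and APL3 by 0.68 (SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.000187 and 0.0108, the latter 0.453 with the spike score at 0.55, SE 0.304).

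The comparison of both treatments with SMX alone called 7384 probe sets, the most of the 6, but with either score it called fewer than both against control. AT1G52070 rose from 3.90 ± 0.7 to 10.1 ± 0.023 (SD, n = 3), a change of 6.15 (SE 0.423), AT4G05150 by 5.74 (SE 0.708), AT5G13030 by 5.48 (SE 0.708) and scpl35, a serine carboxypeptidase-like gene, by 5.34 (SE 0.462). AT2G05540 changed by −5.06 (SE 0.53), GAT1_2.1 by −4.85 (SE 0.727), AT2G25450, of glucosinolate modification, by −4.38 (SE 0.401) and AT4G33666 by −4.27 (SE 0.558). Limma with Benjamini-Hochberg adjustment gave adjusted p from 7.61e-05 to 0.00143 for these 8, 0 of which stayed called with the spike score. AT1G52070 (5.85, SE 0.986), AT2G05540 (−5.55, SE 1.23), GAT1_2.1 (−4.71, SE 1.71) and AT2G25450 (−4.19, SE 0.938) kept their size with it, and AT4G05150 (3.09, SE 1.27), AT5G13030 (3.32, SE 1.41), scpl35 (3.24, SE 0.664) and AT4G33666 (−2.89, SE 1.18) shrank. Of the calls, 3689 were up and 3695 down (32.5% of those tested), with 9446 at an unadjusted p under 0.05. The groups did not overlap for 45.3% of probe sets, where chance gives at most 10%. Of the 7384, 4869 changed by at least 1, and a fit of the probe sets of 1 gene called 3762. The spike score left 138 (63% up) and the actin score 305 (64.9% up), the median size going from 1.24 (median SE 0.238) to 0.85 (0.499) with the spike score, and the spike score was lower by a difference of −4.71 in the arrays with both.

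Starvation genes fell here too, with a median of −1.86 (5 of 5 down, 5 when adjusted over the list alone), while cell wall genes rose by 1.42 (4 up, 4 over the list alone) and nucleotide genes by 0.47 (3 up, 4 over the list alone). Limma's camera gave Benjamini-Hochberg adjusted p = 0.000918, 0.0149 and 0.0317, and adjusted p = 0.146 for each with an estimated correlation. Nucleotide genes did not pass without SMX replicate 1 (adjusted p = 0.0573) or sucrose plus SMX replicate 3 (0.0504), after quantile normalization (0.063), with the spike score (0.0582) or the actin score (0.23, limma's camera, Benjamini-Hochberg). Cell wall genes did not pass with the spike score (0.516), the actin score (0.458) or at a mean log2 value above 4 or above 6 (0.0553 and 0.174), and nucleotide genes did not at those filters (0.219 and 0.244). MCCA changed by −3.77 (SE 0.412), AT4G33150 by −2.14 (SE 0.277), AKINBETA1 by −1.86 (SE 0.255), EXPA8 by 2.53 (SE 0.452), XTH20 by 1.66 (SE 0.278), XTH18 by 1.12 (SE 0.223), AT1G63660 by 0.98 (SE 0.22) and AT2G35040 by 0.87 (SE 0.134). None of these 8 was called with the spike score (limma, Benjamini-Hochberg adjusted p from 0.0958 to 0.666) or the actin score (0.132 to 0.587). AT4G33150 (−1.96, SE 0.646), XTH20 (2.50, SE 0.554), AT1G63660 (1.29, SE 0.501) and AT2G35040 (0.83, SE 0.313) kept or gained size with the spike score, and MCCA (−2.80, SE 0.883), AKINBETA1 (−0.89, SE 0.448), EXPA8 (1.19, SE 0.909) and XTH18 (0.52, SE 0.463) lost some. AT1G16350, IMP dehydrogenase, rose by 0.47 (SE 0.152; limma, Benjamini-Hochberg adjusted p = 0.0433). Its call held only without control replicates 1 or 3 or SMX replicate 2 (9 other arrays, 0.0614 to 0.132), and ended after quantile normalization (0.0758) and with either score (0.41, SE 0.355, adjusted p = 0.656 with the spike score).

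Folate genes split again, and 3 auxin response genes fell. FOLB1 changed by −1.93 (SE 0.236), AT4G30000 by −1.17 (SE 0.161), from 5.19 to 4.02, and AT3G07270, GTP cyclohydrolase, by 1.43 (SE 0.21; limma, Benjamini-Hochberg adjusted p = 0.000595, 0.00101 and 0.00128). IAA29 changed by −3.46 (SE 0.273), GH3.3 by −2.12 (SE 0.352) and LBD29 by −1.98 (SE 0.198), from 4.40 with SMX alone, where the control was 3.04, to 2.42 (limma, Benjamini-Hochberg adjusted p = 0.000111, 0.00228 and 0.00026). None of these 6 genes was called with the spike or the actin score, although with the spike score IAA29 (−3.49, SE 0.64), LBD29 (−2.01, SE 0.464) and GH3.3 (−3.21, SE 0.694) kept or gained size, while FOLB1 (−1.19, SE 0.464), AT4G30000 (−1.0, SE 0.372) and AT3G07270 (1.25, SE 0.486) lost some. The folate list had 3 up and 3 down (3 and 4 when adjusted over the list alone) and the auxin list 0 and 3, also over the list alone. The other lists had limma camera tests with Benjamini-Hochberg adjusted p from 0.139 to 0.737, photosynthesis at 0.308 (0.0402 with the actin score). Peroxidases (median 0.19), glycolysis (1.54), expansins (2.76) and autophagy genes (−1.18) passed the added tests, with limma camera and Benjamini-Hochberg adjusted p from 0.000204 to 0.0147, and adjusted p = 0.0785, 0.382, 0.284 and 0.475 with estimated correlations. Autophagy genes did not pass with the spike score (−0.49) or the actin score (−0.43; limma's camera, Benjamini-Hochberg adjusted p = 0.358 and 0.371), while glycolysis (0.60) and expansins (1.13) shrank but passed with the spike score.

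The target gene AT4G30000 was called for sucrose alone too, from 5.23 ± 0.21 to 4.55 ± 0.17 (SD, n = 3), a change of −0.68 (SE 0.161; limma, Benjamini-Hochberg adjusted p = 0.0173). That call ended without control replicate 3 (adjusted p = 0.0595) or sucrose replicate 2 (0.0652), and with the spike or the actin score (−0.54, SE 0.329, adjusted p = 0.586 and −0.51, SE 0.296, adjusted p = 0.574, limma, Benjamini-Hochberg). Its interaction was −0.49 (SE 0.228; limma, Benjamini-Hochberg adjusted p = 0.861).

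SMX alone and sucrose alone shared 4 calls, the 4 falls of SMX alone, and 0 in opposite directions. They were AT1G76590 (−0.80 and −0.93), UGT85A5 (−0.90 and −0.91), a glycosyltransferase, CHR40 (−1.06 and −1.23), a chromatin remodeller, and AT5G16640 (−0.46 and −0.45), the last 3 named after their values were seen. UGT85A5 ended at 2.15 with SMX and 2.15 with sucrose, AT5G16640 at 2.54 and 2.55 and CHR40 at 2.35 and 2.19, low values with little room to fall further, so near-equal falls from the shared control arrays are no evidence of equal responses. Independent calls would share 1.78 up and 0.463 down, and unchanged groups simulated against the shared control arrays shared 0.04 on average over 100 simulations. Across probe sets, which are not independent replicates, the changes correlated at r = −0.169, against 0.499 simulated, and their covariance was −0.041, against 0.031 simulated, a difference of −0.071. The simulation had no changed groups and no shift common to an array, while the spike score differed from control by 0.731 with SMX and by −4.02 with sucrose. The negative values therefore do not show opposite responses to SMX and sucrose. Control arrays were too few to split, so part of any overlap can come from sharing them. The number shared was 49, 16 or 12 without control replicate 1, 2 or 3, 2 after median centring, 0 at a mean log2 value above 4 or above 6, 1 with the spike score, and 30 without control replicate 1 and sucrose replicate 1 together. AT5G16640 was not called for SMX alone with the spike score or the actin score (limma, Benjamini-Hochberg adjusted p = 0.0872 and 0.0708), at −0.45 (SE 0.061) and −0.46 (SE 0.0614).

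The labelling measures separated the arrays by sucrose. The spike score, the 3′ minus 5′ log2 difference of dap, lys and phe, was 5.53 ± 1.32 (SD, n = 6) without sucrose and 1.17 ± 0.364 (SD, n = 6) with it, a difference of −4.37 with every array without sucrose above every array with it (exact permutation test p = 0.00216, the smallest that 924 arrangements allow; Benjamini-Hochberg adjusted p = 0.00336 over 14 measures). Actin gave 6.14 ± 1.61 and 1.31 ± 0.402, GAPDH 5.64 ± 1.04 and 1.19 ± 0.201 and ubiquitin 2.02 ± 0.181 and 1.34 ± 0.0654 (SD, n = 6 each), with the same exact permutation p = 0.00216 each. The 5′ actin probe set was 7.64 ± 1.6 without and 12.5 ± 0.313 with sucrose, while the 3′ probe set was 13.8 in both (SD, n = 6; exact permutation p = 0.636). Hybridization controls averaged 10.4 ± 0.465 and 9.46 ± 0.764 (SD, n = 6; exact permutation p = 0.0281, Benjamini-Hochberg adjusted p = 0.0328).

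**Figure D5:**
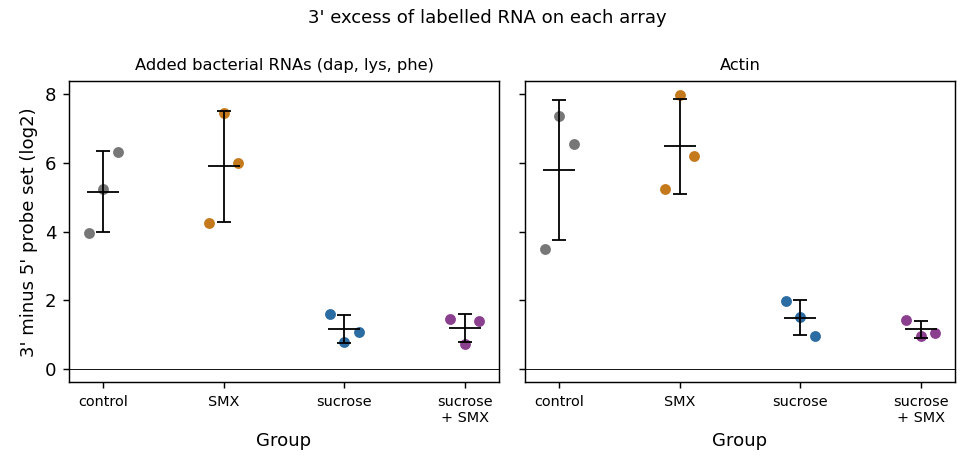
The 3′ minus 5′ log2 difference of the dap, lys and phe transcripts (spike score) and of actin on each of the 12 arrays, with the mean ± SD of 3 arrays per treatment. The spike score averaged 5.53 on the 6 arrays without sucrose and 1.17 on the 6 arrays with it.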

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

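All tests of explanations in this part were chosen only after the results were seen, except those of mixed RNA and of other splits, and the decision rule of the mixing test was changed to an interval after its value was seen, which left its verdict as it was. The rule for intermediate labelling was made stricter after its values were seen, by asking that the array next in score also be next on the first component, and this moved its verdict from met to open. Without sucrose that step turned on SMX replicate 1 at −69.1 against control replicate 2 at −69, a close order. The rule for labelling bias in the third pattern was also changed after its value was seen, by asking that the spike score differ between the groups by more than its SD within them, and this moved its verdict from excluded to open.

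The difference made by SMX itself differed with and without sucrose for 16 probe sets, by the test of the interaction, against a highest other split of 21, and for 1 with the spike score as a covariate, with the median size at 1.53 before and 1.57 after. The genes that met the naming rule were AT2G43620 (interaction 2.91), AT5G40590 (2.31), AT1G74010 (2.25) and AT5G42250 (−1.56), and each lost its call on leaving out any of 7 to 11 of the 12 arrays. The first 2 were not clearly above background without sucrose, so their values are not exact log2 differences. By the same difference the lists for auxin response (median −0.217), methionine and methyl cycle (0.685) and sugar starvation (−0.448) passed limma's camera test with the preset correlation. None passed with an estimated correlation (limma, Benjamini-Hochberg adjusted p = 0.328, 0.21 and 0.373) or with fry (0.237, 0.101 and 0.361). A probe set for 25S ribosomal RNA, kept out of the comparisons as an array control, read 5.65 log2 units higher with sucrose than without, 9.61 ± 3.71 against 3.96 ± 1.07 (SD, n = 6 each; exact permutation p = 0.013, Benjamini-Hochberg adjusted p = 0.0165), although sucrose replicate 1 read 2.38.

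The first pattern weighed is the large number of probe sets that differ between arrays with and without sucrose. Transcripts of Bacillus subtilis, which no seedling makes, also differed in 3′ to 5′ signal by sucrose (exact permutation p = 0.00216), which shows that labelling differed. The 5′ control probe sets of actin and GAPDH, which seedlings make, read 4.89 and 4.63 higher with sucrose, and their 3′ probe sets 0.0622 and 0.174 higher. For these transcripts the values argue against a response of the seedlings alone. They were kept out of the tests, so for the called probe sets a response of the seedlings alone stays open. Within the SMX arrays and the arrays with both, the slope of each probe set on the spike score correlated with its sucrose change at r = −0.308. Of 36 orders of the scores within groups, 3 gave an absolute value as large, the real order included, and the highest of the smaller ones was 0.306. A contribution of labelling bias to the called probe sets therefore remained undecided. Whether labelling bias could be the whole cause was also undecided: 1.22% of the 5336 calls (65) were made again with the spike score, while the median size went from 1.17 (SE 0.238) to 0.762 (SE 0.437) and 96.9% kept their sign, and the score itself follows sucrose, so the covariate removes part of any true response. Adjusted sizes also extend slopes within groups across the gap between them, so a kept size does not exclude labelling. The 64 probe sets called with each of the 2 scores were picked by that outcome, so their count decides nothing about labelling.

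The second pattern is that control replicate 1 and sucrose replicate 1 lie toward each other, at −29.5 and 39.6 on the first principal component, where the other arrays without and with sucrose lie at −69 to −83.5 and 66.8 to 77.4. Intermediate labelling bias stays open: 2 of 2 of these arrays had the spike scores nearest to the other sucrose level (3.95 and 1.58). Arrays with nearly the same scores lay with the rest, however: SMX replicate 1 (4.24) lay at −69.1, and sucrose plus SMX replicates 1 and 3 (1.44 and 1.40) at 66.8 and 73.8. By the rule of its test, RNA of the other group mixed into control replicate 1 was excluded. Probe sets higher and lower with sucrose gave shares of 0.0862 and 0.286, a difference of 0.2 (95% bootstrap interval 0.145 to 0.244). Mixing gives equal shares only where values are proportional to RNA amount, which was not tested. The interval also takes probe sets as independent, so the test cannot rule out mixing. A swap of the 2 arrays was excluded, since each correlated better with its own group than with the other, by 0.0162 and 0.029.

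The third pattern is the set of calls between both treatments and sucrose alone. By the rule of its test, a contribution of labelling bias stays open. The spike score was 1.15 ± 0.408 with sucrose and 1.19 ± 0.404 with both (SD, n = 3), a difference of 0.0402. This is too little for the covariate to alter sizes, so the 32 of 43 calls made again with it decide nothing about labelling. The near-equal scores themselves argue against a mean difference in labelling behind these calls, as far as the spike score measures it. GAPDH gave 1.32 ± 0.148 and 1.06 ± 0.169 (SD, n = 3), so a bias that the spike score misses stays open. The actin score differed by −0.333, and 27 calls were made again with it.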

How the results depend on the processing

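The covariate fits and the fit without control replicate 1 and sucrose replicate 1 together were chosen after seeing the data. Except where construction shows it (fewer probe sets or arrays, or a larger change asked for), the cause was not tested. Of the 19 calls of SMX alone, 14 had a higher mean under 5.

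For SMX alone, 19 calls became 9 after median centring, 0 at a mean log2 value above 4 and 0 above 6, 40 without the 2 arrays, 10 among probe sets of 1 gene, 7 at a change of at least 1, and 0 in a fit of the 6 arrays compared. For sucrose alone, 5336 became 65 with the spike score, 251 with the actin score, 2691 with 1 gene, 3328 at a change of at least 1 and 1856 in the 6-array fit. For both against control, 6180 became 287, 441, 3108, 3923 and 3530 in the same order. For both against SMX alone, 7384 became 138, 305, 3762 and 4869 in the first 4 of these. For both against sucrose alone, 43 became 66 above a mean of 4, 193 with array weights, 22 with 1 gene and 0 in the 6-array fit. For the interaction, 16 became 8 after quantile normalization, 1 with the spike score, 2 with the actin score, 29 without the 2 arrays and 6 with 1 gene. The median size of the called probe sets, with its median SE, went with the spike score from 1.17 (0.238) to 0.762 (0.437) for sucrose alone, from 1.19 (0.236) to 0.839 (0.433) for both against control and from 1.24 (0.238) to 0.852 (0.499) for both against SMX alone. For the interaction it was 1.53 (0.192) without a score, 1.57 (0.205) with the spike score and 1.54 (0.203) with the actin score, 100% keeping their sign, so there the calls were lost without a smaller change. The F test's 7043 became 109 with the spike score, 165 with the actin score and 3581 with 1 gene.

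Of the 10 lists, the 0 passed for SMX alone became 1 after median centring and 1 without the 2 arrays. The 3 for sucrose alone became 1 above a mean of 6, 1 with the spike score, 1 with the actin score and 0 with an estimated correlation. The 3 for both against control became 1, 1, 1 and 0 in the same order, and 6 with fry. The 2 for both against sucrose alone became 1 above a mean of 4, 1 above 6, 1 without the 2 arrays, 0 with an estimated correlation and 0 with fry. The 3 for both against SMX alone became 1 above 4, 1 above 6, 1 with the spike score, 0 with an estimated correlation and 5 with fry. The 3 for the interaction became 0 above 4, 0 with an estimated correlation and 0 with fry. The 4 calls shared by SMX alone and sucrose alone became 2 after median centring, 0 above a mean of 4, 0 above 6, 1 with the spike score and 30 without the 2 arrays.

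Leaving out 1 array at a time gave 9 to 70 calls for SMX alone, 3284 to 6399 for sucrose alone, 4557 to 6999 for both against control, 26 to 52 for both against sucrose alone, 5985 to 7717 for both against SMX alone, 7 to 48 for the interaction and 5847 to 7708 for the F test. Lists passed numbered 0 to 2, 3 to 3, 3 to 3, 1 to 2, 2 to 3 and 1 to 4 in the order of the 6 comparisons, and shared calls 3 to 49.

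With a replicate block, SMX alone had 5 calls, both against sucrose alone 28, the interaction 1 and the overlap 2. It ended 9 of 98 gene calls and 0 of 14 list calls. The 9 were the 4 named interaction calls, AT2G43620, AT5G40590, AT1G74010 and AT5G42250 (limma, Benjamini-Hochberg adjusted p = 0.117, 0.109, 0.091 and 0.112), AT2G16630 for SMX alone (0.124), EXPA8 for both against control (0.0669), and AT4G38080, AT5G24580 and AT1G76590 for both against sucrose alone (0.069, 0.107 and 0.107). The numbers do not pair the arrays in the design text. Deviations of arrays with the same number correlated at r from −0.36 to 0.223, and 8 of 12 arrays correlated best with their own number. How many would do so by chance was not computed, so an effect shared by arrays of 1 number stays open.

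Of the 98 gene calls, XTH33 for sucrose alone turned direction with the spike score (−0.426), and that score ended 84 others. The actin score ended 79, quantile normalization 8, median centring 1, array weights 2, the trend and robust prior 0, and leaving out the 2 arrays 10. A mean above 4 ended 4 of the 93 that could be tested and a mean above 6 ended 1 of 62. Leaving out any 1 array ended 16. Of the 14 list calls, the spike score ended 7, the actin score 7, a mean above 4 or above 6 ended 8 each, quantile normalization 2, array weights 1, leaving out the 2 arrays 3 and any 1 array 5.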

Other observations

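The F test comparison of splits that keep the sucrose levels apart was chosen only after the result was seen, and the other tests of splits were chosen before.

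GSTU25, a glutathione transferase, was 3.65 ± 0.3, 3.51 ± 0.053, 5.11 ± 0.4 and 6.52 ± 0.37 in control, SMX, sucrose and both (SD, n = 3), and rose by 3.01 when sucrose was added to SMX (SE 0.248). EXPA7 rose by 3.93 for both against control (SE 0.307) and by 4.22 for both against SMX alone, and APL3, a subunit of ADP-glucose pyrophosphorylase in starch synthesis, by 0.67 for both against SMX alone (limma, Benjamini-Hochberg adjusted p = 0.00933). AT3G09630, of the ribosome, rose by 0.89 for both against SMX alone (limma, Benjamini-Hochberg adjusted p = 0.0245). For both against SMX alone, none of these 4 was called with the spike score (limma, Benjamini-Hochberg adjusted p = 0.0686 for GSTU25, 0.0542 for EXPA7, 0.561 for APL3 and 0.599 for AT3G09630), at 3.16 (SE 0.579), 4.26 (SE 0.72), 0.515 (SE 0.346) and 0.81 (SE 0.587). With the actin score GSTU25 and EXPA7 were called (0.0473 and 0.0363, limma, Benjamini-Hochberg), and APL3 and AT3G09630 were not (0.618 and 0.78).

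Other splits of the 6 arrays of a comparison into 3 and 3 called fewer probe sets than the real one for sucrose alone (5336, highest other 2), both against control (6180, highest other 1), both against sucrose alone (43, highest other 5) and both against SMX alone (7384, highest other 0), the real split being the 1 as large in each. For SMX alone 3 of the 10 splits called as many as the real 19 or more, the highest other being 23. The real split passed 0, 3, 3, 2 and 3 lists for SMX alone, sucrose alone, both against control, both against sucrose alone and both against SMX alone, the highest other splits 1, 1, 3, 2 and 3, and 10, 1, 2, 4 and 2 splits passed as many. With 10 splits in each comparison, these are too few for a share under 0.05.

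For the interaction, 100 of 200 distinct splits were drawn that moved arrays only within their sucrose level. Of these, 3 gave a count as large as the real 16 (highest other 21) and 4 passed as many lists as the real 3 (highest other 3), the real split included. For the F test 1 of 100 splits was as large as the real 7043, and the highest other was 67. When arrays were moved only within their sucrose level for the F test, 100 splits called 6338 to 7393, and 18 were as large as the real count, the real split included. The F count thus follows the division by sucrose and says nothing of SMX.

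The thr transcript of Bacillus subtilis had a 3′ minus 5′ difference of 9.58 ± 0.644 without sucrose and 2.80 ± 1.22 with it (SD, n = 6 each; exact permutation p = 0.00216). The weights that limma estimated for the arrays ranged from 0.318 to 3.19.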
